A study of Gallus gallus with 7 samples.

How the data were processed

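The series holds 7 libraries from sorted chicken vagal neural crest cells: 1 RNA-seq library at Hamburger and Hamilton stage 10 (HH10) and 6 chromatin libraries at HH18. The 6 chromatin libraries are 2 biotin pull-downs of sox10, 2 of tfap2B and 2 inputs. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates of a group came from separate embryos or pools, so p-values measure only the spread between these samples, which may be technical.

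Per the submitters' processing notes, the genome build was galGal5 and the tools included STAR 2.4.2a, Subread 1.4.5, featureCounts, Bowtie, DESeq2 and DiffBind, with no order or role given. How the chromatin regions were called, and on which libraries, is not given in the sources used here. The deposited chromatin table lists 25469 regions, of which 25446 have an end minus start of 500 bp and 23 another width. Coordinates are printed as the table gives them. The sources do not state whether its starts count from 0 or 1, and 266 starts on unplaced sequences lie below 0. A total of 13888 regions lie on 34 placed chromosomes, and 11581 (45.5%) on 6630 unplaced sequences.

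The deposited chromatin table is named as raw counts, but its values are a signal: whole reads multiplied by 1 constant per library. With a tolerance of 0.01 read, 100.0% of the values were whole multiples of the value of 1 read. That value was 1.20 and 2.34 for the sox10 libraries, 0.895 and 2.08 for the tfap2B libraries, and 0.695 and 0.363 for the inputs. How the authors set the constants is not given in the sources used here. Every region has at least 1 read in every library, so a listed 1 can stand for 0 or 1. The values are called scaled reads here. The deposited gene table holds whole-number counts per Ensembl gene, not normalized, per the file headers and values. The column for the HH10 library occurs 2 times with identical values and was used 1 time, and 21 columns of other samples were not used. The strand setting of the gene counting is not given in the sources used here, so reads of overlapping genes on opposite strands could not be told apart.

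The tests had been planned for raw counts, with edgeR. Because the unit was a scaled signal, the main test was limma 3.58.1 with an intensity trend on log2(scaled reads + 1), with all 6 libraries in 1 fit, no covariate, and Benjamini-Hochberg adjusted p under 0.05. The fit has 3 residual degrees of freedom. Log2 differences are on this scale, which understates the change of low regions. A low-read filter on the recovered reads (filterByExpr of edgeR 4.0.16) left 25281 regions, 13885 of them placed, and removed 188. The edgeR quasi-likelihood test on recovered reads was run as an added alternative. It called 2548 regions higher and 2900 lower for sox10 against input, 1923 and 2404 for tfap2B against input, and 0 between the factors.

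Alternatives were total reads per library, DESeq2 1.42.0 size factors, upper quartile factors, a DESeq2 Wald test on recovered reads, no filter, a filter of 20 reads in 2 libraries, a replicate block, only the 2 groups compared, adjusted p under 0.01, a test against a log2 difference of 1, and leaving out each library. The scaling alternatives were run inside the limma fit. These were fixed before the data were examined. EdgeR with TMM factors was the planned test. The limma main test, and edgeR and TMM factors as alternatives to it, were set after the unit was seen. A pseudocount of 10, 1 variance weight per group, placed chromosomes only and a crossed block were chosen after seeing the data.

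The test was run on simulated data with 250 changed regions per fold size over 5 runs of 25281 regions. Against input, 1.6% of 8-fold and 5.6% of 16-fold changes were recovered for sox10, and 1.2% and 12.4% for tfap2B, with 0 false calls. Between sox10 and tfap2B the fit with inputs recovered 0% of 16-fold changes. The fit without inputs recovered 40% of 4-fold and 87.2% of 8-fold changes, with at most 4 false calls in a run. In each run only a small share of the regions changed, and all regions of a group had the same SD. In the data the main fit called 4660 regions higher and 5632 lower for sox10 against input. The recovery rates and false calls therefore hold for the simulated setting and do not give the power or error rate in the data.

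Regions to name were chosen by a rule fixed before the data were examined. It took, per comparison and direction, the 8 called regions with the largest log2 difference, a mean at or above the median, no overlap between the libraries of both groups, and a nearest transcription start site (TSS) of a gene within 100 kb, 1 region per gene with the nearest TSS. Regions inside the same gene can therefore both be named where their nearest TSSs differ. The planned mean log2 CPM and CPM were replaced by log2(scaled reads + 1) and scaled reads, and a named gene by a gene with an Ensembl ID. The files do not pair the IDs with symbols, and 0 of 24881 IDs matched the symbol table of another assembly that was at hand. Gene lists and lists of HH10 levels were therefore not analysed here. The sox10, tfap2B and FOXD3 genes could not be picked out by name. Whether any gene given by its ID here is among them was not determined. Motif content was not analysed here because no genome sequence of this build was used.

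Gene coordinates of the same build came from the deposited gene table. Placed regions were classed as within 1 kb of a TSS (called promoter here), else exon, else intron, else intergenic. Promoter shares have 95% Wilson intervals and were compared with Fisher's exact test, two-sided. Regions are not replicates. For HH10 levels, counts were scaled by the library total to CPM, and the median CPM of genes near regions was ranked among 10000 random lists of the same size drawn from genes nearest to any tested region. Intervals of single CPM values are exact Poisson intervals at 95% and cover counting error only. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used.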

Results

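Vagal neural crest cells, which leave the hindbrain-level neural tube and contribute to the enteric nervous system among other tissues, were sorted from chicken embryos by a citrine reporter. At HH10 the NC2 reporter had been electroporated at HH4, and at HH18 the E2 reporter at HH8. At HH18 the transcription factors sox10 and tfap2B, both known regulators of neural crest, carried an Avi tag that the enzyme BirA biotinylates, so that streptavidin beads could pull down the chromatin they bind without an antibody. The chromatin set had 2 libraries each of sox10, tfap2B and input, and the RNA set 1 library. Reads in regions numbered 2533921 and 1366132 for sox10, 3498728 and 1405830 for tfap2B, and 7989029 and 13921317 for input. The HH10 RNA library held 28777461 counts.

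The robust within-group SD of a region on the log2 scale was 0.36 for sox10, 0.63 for tfap2B and 1.26 for input, so by this measure the inputs spread most. An offset between the libraries of a group over all regions enters this SD, and the placed medians differed most between the inputs (106 and 206). Across placed regions, which are not independent replicates, Pearson's r of the log2 values was 0.81 between the sox10 libraries, 0.69 between the tfap2B libraries and 0.70 between the inputs. The median placed region had 124 and 122 scaled reads in the sox10 libraries, 141 and 121 in the tfap2B libraries, and 106 and 206 in the inputs.

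The comparison of sox10 with input asks where sox10 chromatin is enriched. In total 4660 regions were higher in sox10 than in input, 1973 of them placed, and 5632 were lower, 2195 of them placed. Over the 1973 placed regions the median was 205 and 255 scaled reads in the sox10 libraries, against 6.25 and 0.726 in the inputs. The medians of all placed regions were 124 and 122 in sox10 and 106 and 206 in input, so these calls come more from low input than from high sox10 signal. Of these regions 50.2% were intergenic and 35.5% intronic, and their median distance to a TSS was 17.9 kb. Only 9.43% lay within 1 kb of a TSS (95% Wilson interval 8.22 to 10.8%), against 57.8% of the other placed regions (Fisher's exact odds ratio 0.0759). The profile of the inputs enters this contrast. Of the 493 placed regions with at most 3 reads in both inputs, 3.25% were promoters, and 100% were called above input for sox10. Of the placed regions lower in sox10, 52.9% were promoters, with a median TSS distance of 0.804 kb, but at adjusted p under 0.01 the share was 35.5%, below that of the other placed regions (51.3%).

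Among the 8 named regions above input for sox10, the largest difference was at chromosome 1, 153949552 to 153950052 (galGal5), an intergenic region 31.2 kb from the nearest TSS. It had 6616 ± 4227 scaled reads in sox10 (SD, n = 2) and 42.0 ± 58.4 in input (SD, n = 2), a log2 difference of 8.93 ± 1.50 (SE, limma adjusted p = 0.0056). A region in an exon of ENSGALG00000012290 (chromosome 1, 51090792 to 51091292) followed with a log2 difference of 8.44 ± 1.95 (SE, limma adjusted p = 0.0149). It had 2413 and 11125 scaled reads in the sox10 libraries and 163 and 0.363 in the inputs. On the same chromosome a promoter region at 51067475 to 51067975 differed by 6.74. Intergenic regions at 113476277 of chromosome 2 and 5131580 of chromosome 23 differed by 6.59 and 5.35. Intronic regions at 57427179 of chromosome 1 and 56654 of chromosome 12 differed by 5.64 and 5.32, and an exonic region at 108690314 of chromosome 3 by 6.18. Low counts in 1 or both inputs entered these differences. Inputs 1 and 2 had 69 and 1 reads at 57427179, 135 and 2 at 56654, and 1 and 5 at 108690314. They had 42 and 1 reads at 51067475, 29 and 1 at 113476277, and 5 and 110 at 5131580. At 108690314 the sox10 libraries had only 1.05 and 1.58 times their placed median, so that difference came mainly from low input. The edgeR test did not call 4 of these 8 regions. Those lower than input included an intergenic region at 5638279 of chromosome 20 (log2 difference -4.46 ± 0.73, SE), an intron at 336347 of chromosome 2 (-4.18) and an exon at 105038301 of chromosome 3 (-4.14).

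The median log2 difference of all regions between sox10 and input was -0.40, and other scalings placed it between -0.15 and 0.35. The share of higher among called regions, 45.3%, was 71.6% with total reads, 64.1% with DESeq2 factors and 72.1% with upper quartile factors. Single libraries moved the counts by over 1.5 times: 965 higher and 972 lower without sox10 replicate 1, 462 and 203 without sox10 replicate 2, 2985 higher without tfap2B replicate 1, 2951 higher without tfap2B replicate 2, 8864 lower without input replicate 1, and 7095 higher without input replicate 2.

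The comparison of tfap2B with input asks the same for tfap2B. It gave 2721 higher regions, 1418 of them placed, and 4401 lower, 1343 of them placed. The placed higher regions were again mostly intergenic (47.8%) or intronic (33.9%), at a median of 15.4 kb from a TSS. Promoters made up 13.8% of them (95% Wilson interval 12.1 to 15.6%), against 55.2% of the other placed regions (Fisher's exact p = 2.36e-210). The tfap2B libraries had a median of 94.0 and 99.96 scaled reads in these regions, and the sox10 libraries 202 and 246. The tfap2B medians thus lay below those of all placed regions (141 and 121). As a set, these calls come mainly from low input, with medians of 3.47 and 1.09 against 106 and 206. The 493 placed regions with at most 3 reads in both inputs were 3.25% promoters, and 92.5% of them were called above input for tfap2B. The low promoter share thus follows the inputs at least in part and does not by itself show where tfap2B binds. Single regions named below had far higher tfap2B signal. Among the placed regions lower than input, 40.6% were promoters, fewer than of the other placed regions (52.1%), and 19.9% exonic. Within 5 kb of a TSS the order turned, with 67.7% against 64.3%.

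For tfap2B the named regions were led by an exonic region of ENSGALG00000016680, at chromosome 3, 108690314 to 108690814. It had 3857 ± 2254 scaled reads in tfap2B (SD, n = 2) and 1.25 ± 0.79 in input (SD, n = 2), a log2 difference of 10.65 ± 0.66 (SE, limma adjusted p = 0.0056). Another exonic region of that gene, 108710618 to 108711118, whose nearest TSS is that of another gene, differed by 10.44 ± 1.44 (SE, limma adjusted p = 0.0073). Of the 8 named higher regions, 6 were also named for sox10. A promoter at 49766513 of chromosome 2 was not; it differed by 5.43 and had 3381 scaled reads in tfap2B and 3189 in sox10. The edgeR test did not call 5 of these 8 regions. Regions lower than input included a promoter at 403148 of chromosome 2 (-5.05 ± 0.92, SE), an intron at 75007009 of chromosome Z (-4.83) and an intergenic region at 36619 of chromosome 32 (-4.61).

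No region was called for tfap2B against input without tfap2B replicate 1 or without tfap2B replicate 2 (0 higher and 0 lower in each case). The smallest adjusted p was then 0.066 and 0.0576. The other libraries moved them too: 1159 higher and 2296 lower without sox10 replicate 1, 1171 and 2371 without sox10 replicate 2, 6166 and 6684 without input replicate 1, and 6122 higher without input replicate 2. The share of higher among called regions was 38.2% as deposited, 49.3% with TMM factors, 52.7% with DESeq2 factors, 64.3% with upper quartile factors and 68.5% with total reads, with median differences of all regions from -0.14 to 0.65.

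**Figure D1:**
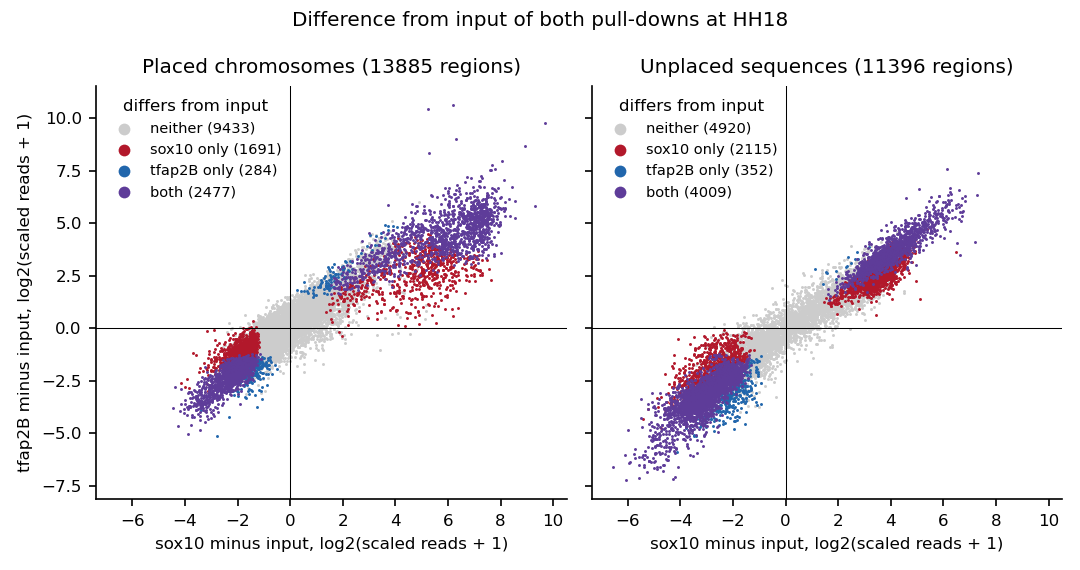
Log2 difference from input of sox10 (horizontal axis) and tfap2B (vertical axis), on the log2(scaled reads + 1) scale, 1 point per tested region, coloured by which comparison called it. Of the tested regions 13885 are placed and 11396 unplaced. Both axes use the same inputs, so the points would rise together without any change: the correlation is 0.95, against 0.86 in simulated unchanged groups.

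Many of the regions above input were called for both factors, and much of this overlap can come from the inputs that both comparisons share. Of the regions above input, 2607 were called for both, which is 95.8% of the tfap2B regions and 55.9% of the sox10 regions, and 3879 were below input for both. Independent lists of these sizes would share 502 and 980. In groups simulated without any change, each set against the same inputs, no region was called, so equally long lists of the top regions by p were taken. They shared 2264 regions above input on average over 50 runs (at most 2296) and 3469 below input (at most 3515). The log2 differences of both factors had a covariance of 5.78 across regions, against 0.797 in the simulation, a difference of 4.99, and a correlation of 0.95 against 0.86. With input 1 for sox10 and input 2 for tfap2B, so that no library entered both differences, the covariance was 5.09, and 4.48 the other way round (computed after the data were seen). The inputs have a regional profile in common (Pearson's r 0.69), which enters these covariances and the difference of 4.99, so they do not show agreement beyond the inputs. Without the inputs, the sox10 and tfap2B libraries correlated at 0.64 to 0.84 across all regions, which are not independent replicates. Across placed regions alone they correlated at only 0.27 to 0.58. None of the libraries is a pull-down without a tagged factor, so binding by both factors was not separated from background common to the pull-downs. A split leaves only 1 input per factor, and the calls were not repeated with it, so part of the excess in the counts may come from the shared inputs. The 2607 shared regions became 4334 with total reads, 734 at adjusted p under 0.01, 765 without sox10 replicate 1, 417 without sox10 replicate 2, 5952 without input replicate 1, 5475 without input replicate 2, and 0 without tfap2B replicate 1 or 2. The 3879 below input became 837 and 198 without sox10 replicates 1 and 2, and 0 without tfap2B replicate 1 or 2.

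The direct comparison of sox10 with tfap2B asks where the factors differ. With all 6 libraries in the fit, limma called 0 regions higher and 0 lower; 1059 had an unadjusted p under 0.05, edgeR also called 0, and the DESeq2 Wald test called 144 higher and 3 lower. On simulated data this fit recovered 0% of 16-fold changes between the factors, so a count of 0 does not show that the factors bind alike. Without the inputs, an alternative fixed before the data were examined, 625 regions were higher in sox10, 621 of them placed, and 26 were higher in tfap2B, 13 of them placed.

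In the 621 placed regions the median was 242 and 297 scaled reads in sox10, 40.3 and 54.1 in tfap2B, and 3.47 and 0.363 in input. Of them 612 were also above input for sox10 and 364 (58.6%) above input for tfap2B. Promoters made up 4.35% (27 of 621), against 46.2% (6 of 13) of the placed regions higher in tfap2B (Fisher's exact p = 1.66e-05). With only 13 regions the 46.2% has a wide Wilson interval, 23.2 to 70.9%. The test against the other placed regions (51.0%, Fisher's exact p = 0.787) therefore cannot show whether the shares differ. Of the 13 regions, 5 lie in 1 gene, none of them a promoter, and 6 of the 8 outside it are promoters. The 4.35% of the sox10 regions lay far below the 53.1% of the placed regions other than those 621. The contrast thus comes at least in part from the few promoters among the sox10 regions. An intergenic region at 32290081 of chromosome 6, 1.42 kb from a TSS, had 457 ± 76.5 scaled reads in sox10 and 96.1 ± 12.2 in tfap2B (SD, n = 2), a log2 difference of 2.23 ± 0.34 (SE, limma adjusted p = 0.0202). Introns at 19290262 of chromosome 11 and 1303769 of chromosome 17 differed by 2.22 and 2.01, and an intergenic region at 2483574 of chromosome 24 by 2.19. Of the 13 placed regions higher in tfap2B, 6 were above input for tfap2B, and of the 13 unplaced ones 1 was. Regions higher in tfap2B than in sox10 included promoters at 613999 of chromosome 16 (-2.30) and 6578946 of chromosome 19 (-1.97). The promoter of chromosome 16 had 451 and 279 scaled reads in tfap2B, below the 1422 and 524 of the inputs. The counts were 0 and 0 without either sox10 library and at adjusted p under 0.01, 1490 and 322 without tfap2B replicate 1, and 4116 and 3220 without tfap2B replicate 2.

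All 5 regions inside ENSGALG00000016680 (chromosome 3, 108690400 to 108715816, minus strand) overlapped its exons and were higher in tfap2B than in sox10 in the fit without inputs (log2 differences, sox10 minus tfap2B, of -5.21 to -2.12); the group was singled out after its values were seen. The region at 108710618 had 18945 and 7940 scaled reads in the tfap2B libraries, 323 and 339 in the sox10 libraries and 56.3 and 0.363 in the inputs. The 2 regions nearby but outside the gene, at 108718482 and 108722451, had log2 differences of 0.37 and 0.41 that did not pass the test.

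**Figure D2:**
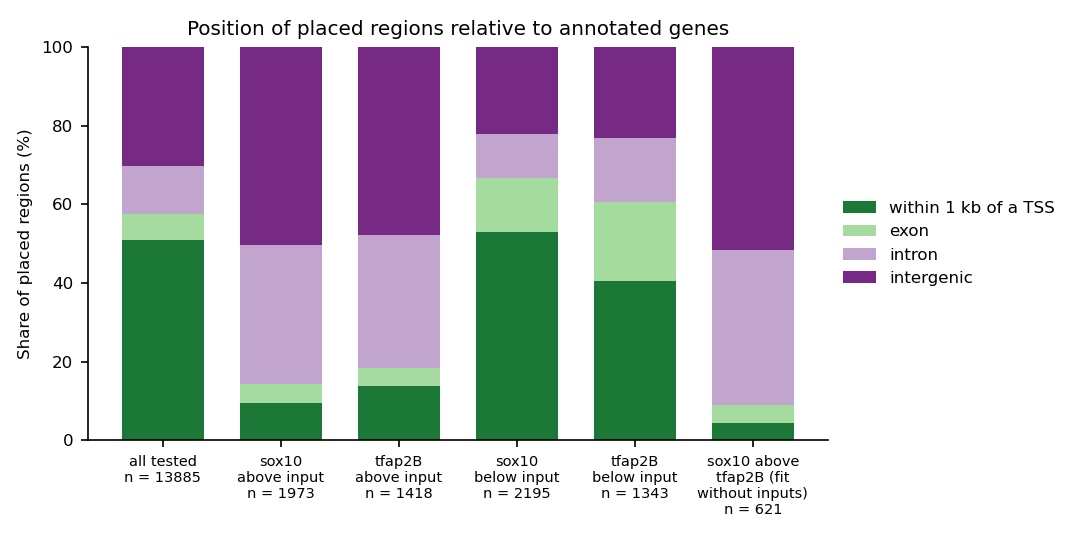
Share of placed regions (%) by position class for all tested regions and for the called sets, with the number of regions under each bar. Promoters fall from 51.0% of tested regions to 9.43% and 13.8% of those above input for sox10 and tfap2B. Placed regions with at most 3 reads in both inputs were 3.25% promoters, so the profile of the inputs enters these shares.

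**Figure D3:**
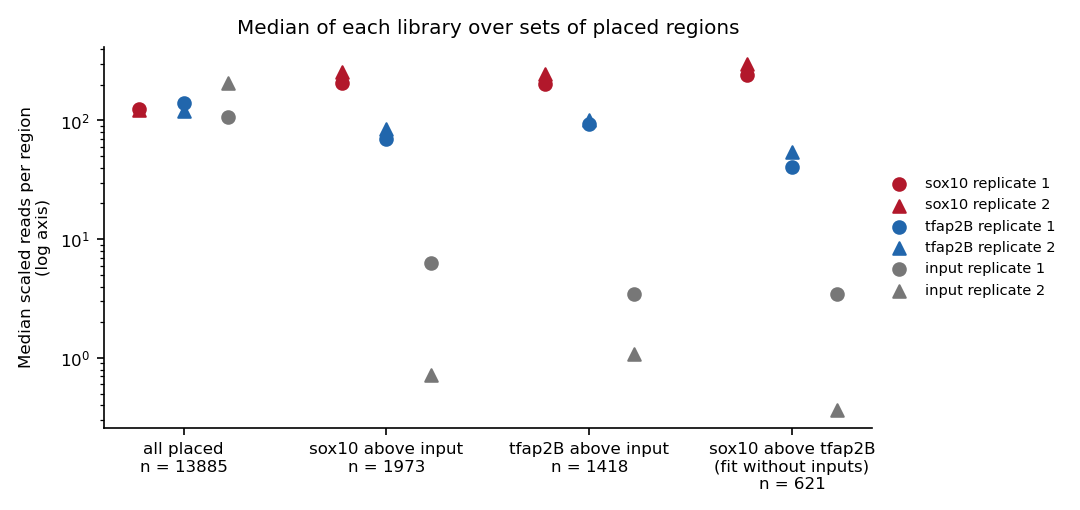
Median scaled reads per region (log axis) of each library, 1 point per library, over sets of placed regions. In the regions above input for tfap2B the sox10 medians (202 and 246) lie above the tfap2B medians (94.0 and 99.96).

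**Figure D4:**
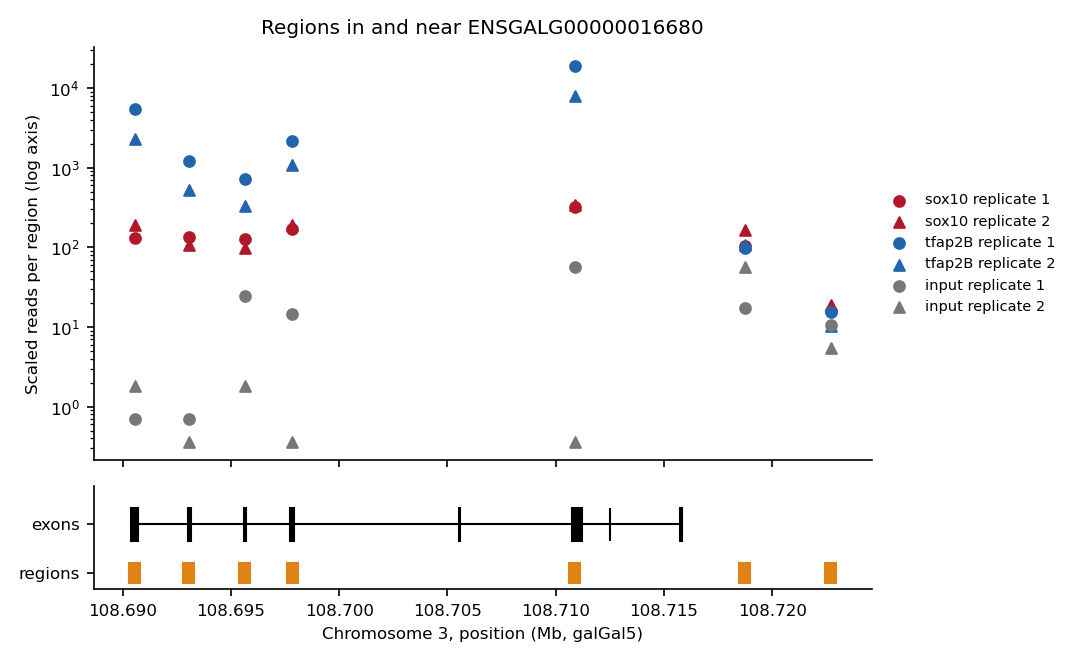
Scaled reads per region (log axis) of the 6 libraries over ENSGALG00000016680 on chromosome 3 (galGal5, position in Mb), with its 8 exons in black and the regions in orange. The 5 regions over exons are higher in both tfap2B libraries than in both sox10 libraries.

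At HH10, before the stage of the chromatin libraries, 13410 of 24881 genes had at least 1 count and 12354 at least 10. The 20 genes with the most counts took 4.22% of all counts and the top 100 took 11.8%. ENSGALG00000016680 had 253 CPM (exact Poisson interval 247 to 259) and ENSGALG00000012290 had 818 CPM (807 to 828), rank 80 of all genes. There is 1 RNA library, so these levels have no replicate check.

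Genes nearest to regions above input had a lower median level at HH10 than genes nearest to any tested region, although single genes such as ENSGALG00000012290 were high. The median was 6.78 CPM for the 1531 genes near sox10 regions and 7.61 CPM for the 1157 near tfap2B regions, against 19.4 CPM for the 10098 genes nearest to any tested region. Both lay below all 10000 random lists (percentile 0). With regions assigned to the genes whose body or preceding 5 kb they overlap, the percentiles were 0.08 and 2.59. For regions outside promoters alone the medians were 6.29 and 6.60 CPM against 5.18 CPM for genes nearest to such regions, at percentiles 96.0 and 95.3. For promoters alone they were 10.3 and 17.1 CPM against 33.6 CPM, at percentiles 0 and 0.01. Genes near regions below input also had low medians, 12.2 CPM for sox10 and 2.88 CPM for tfap2B (percentile 0 for both), so a low level was not particular to regions above input. Outside promoters their medians were 2.17 and 0.764 CPM, again at percentile 0.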

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

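Of the tests in this part, those of equal depth and of matched reads were written before their results were seen, and all others only after the result was seen.

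The factors differed from each other in the fit without inputs, where 625 regions were higher in sox10 and 26 higher in tfap2B, although the fit with inputs called 0. The explanation by depth of the pull-down libraries is argued against: with all 4 libraries thinned to 1366132 reads, the median of 5 draws was 526 called regions (456 to 643). Spread between the inputs that enters the shared error is a candidate explanation for the 0: with the inputs kept and 1 variance weight per group, 460 regions were called. With 1 library left out, only the other pair gives the spread, and the number of calls followed which pair that was. Without sox10 replicate 1 or 2 no region was called, and the median SE of the 625 regions rose from 0.44 to 0.75 and 0.77 (median log2 difference 2.52 with all 4 libraries, 2.68 and 2.34 without). Without tfap2B replicate 1 or 2 the SE was 0.35 and 0.37, and 1490 and 4116 regions were higher in sox10 and 322 and 3220 higher in tfap2B. A difference in binding between the factors remains open.

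Inside ENSGALG00000016680 the 5 exonic regions at 108690314, 108692806, 108695387, 108697580 and 108710618 of chromosome 3 differed between the factors by -4.47, -2.74, -2.12, -3.07 and -5.21 (sox10 minus tfap2B, log2, fit without inputs). More copies of the sequence in all DNA of these cells were not seen as raised input: over these regions the inputs had a median of 0.0695 times that of placed regions. Input levels varied by region, with 493 placed regions at 3 reads or fewer in both inputs. A value below the placed median therefore cannot exclude extra copies. Reads from introduced construct DNA that carries the coding exons stay open. The overlap with exons led to this explanation, so it is no test of it. The tfap2B signal of the 5 regions followed the length of the exon they overlap (Spearman's rho 1), as in 0.0083 of all 120 orders, but the sox10 signal did so as well (rho 0.9, 0.0417 of the orders), so the test does not set the tfap2B libraries apart. The exons without a region, of 61, 27 and 87 bp, are the shortest of the 8. The low input would count against construct DNA only if the input cells carried the construct, which the labels do not say. The regional differences in input limit this too. Construct DNA and binding of tfap2B to the gene itself therefore both stay open.

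Regions above input on unplaced sequences behaved unlike those on placed chromosomes: of 2687 called for sox10, 4 (0.149%) were also called between the factors without inputs, against 617 of 1973 placed (31.3%). Too few reads on unplaced sequences is argued against, since among regions with 200 to 500 pull-down reads the share called was 33.1 times higher on placed chromosomes (474 of 8472 against 7 of 4142). Signal common to both pull-downs stays open, because its 2 values point opposite ways, and the count of 4 is the pattern itself and no test of it. Of the 2687 regions, 48.0% were also called for tfap2B over input, fewer than the 66.8% on placed chromosomes, but the median log2 difference between the factors was smaller (0.653 against 1.599). Over these 2687 regions the tfap2B replicates had medians of 70.7 and 127 scaled reads, against 69.8 and 85.4 over the 1973 placed ones. Whether this gap between the tfap2B replicates lowered the number of calls on unplaced sequences was not tested. The sources used here do not say what these sequences hold, so no biological explanation was tested.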

How the results depend on the processing

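Of the settings here, edgeR and TMM factors belonged to the planned test and became alternatives after the unit of the data was seen. A pseudocount of 10, 1 variance weight per group, placed chromosomes only and the crossed block were chosen only after the data were seen. So were the split by promoter and the other thresholds for regions below input. The further settings for shared regions and all changes to the fit without inputs were also chosen then. The naming rule kept called regions with large differences and no overlap between the libraries of both groups. Their direction could therefore not turn when a library was left out, and had little room to turn in other settings. The 8 named regions per direction gave 32 results against input, on 25 distinct regions. All kept their direction; of 480 values over 15 settings 455 stayed past the threshold and 25 did not, and of 192 values with a library left out 139 stayed and 53 did not. Regions above input for sox10 numbered 2548 with edgeR, 3030 with only the 2 groups, 1553 at adjusted p under 0.01 and 2292 tested against a log2 difference of 1, and those below input 2449 with total reads, 2780 with DESeq2 factors, 2245 with upper quartile factors, 2900 with edgeR, 1349 at 0.01, 1647 against a log2 difference of 1 and 3327 with 1 variance weight per group. For tfap2B the higher regions numbered 4688 with total reads, 1230 with only the 2 groups, 747 at 0.01 and 1142 against a log2 difference of 1, and the lower ones 2157 with total reads, 2619 with DESeq2 factors, 2159 with upper quartile factors, 2894 with TMM, 2404 with edgeR, 2858 with only the 2 groups, 1058 at 0.01, 1421 against a log2 difference of 1 and 2116 with variance weights. Between the factors the 0 and 0 became 144 and 3 with the DESeq2 Wald test (3431 regions had no adjusted p), 625 and 26 with only the 2 groups and 368 and 92 with variance weights. The fit without inputs (625 and 26) gave 0 and 0 at 0.01 and against a log2 difference of 1, 1123 and 144 on placed chromosomes only, 153 lower with the DESeq2 Wald test and 50 lower with a pseudocount of 10. Shared regions above input (2607) numbered 4334 with total reads, 1188 with only the 2 groups, 734 at 0.01 and 1109 against a log2 difference of 1, and those below (3879) 1648 with total reads, 1915 with DESeq2 factors, 1538 with upper quartile factors, 2403 with TMM, 1995 with edgeR, 853 at 0.01, 1070 against a log2 difference of 1 and 1922 with variance weights. A stricter threshold or a tested log2 difference lowers a count by construction; for the other settings the cause was not tested. Leaving out 1 library, with the lone sample assumed to vary like the other groups, gave 462 to 7095 higher and 203 to 8864 lower for sox10 against input, 0 to 6166 and 0 to 6684 for tfap2B against input, 0 and 0 to 2 between the factors, 0 to 4116 and 0 to 3220 in the fit without inputs, and 0 to 5952 and 0 to 5789 for shared regions. The labels do not say whether replicate numbers pair the samples, and the numbers as given showed no sign of it. Differences between replicates correlated at 0.05 between sox10 and tfap2B, -0.03 between sox10 and input and -0.27 between tfap2B and input. With the replicate block the counts were 3668 and 4310 for sox10, 1982 and 3307 for tfap2B, 0 and 0 between the factors, 1922 and 2866 for shared regions, and 1173 and 198 in the fit without inputs. With the input numbers crossed in the replicate block, 3544 regions were higher and 4427 lower for tfap2B, against 2721 and 4401 in the main fit. A pairing of tfap2B and input in crossed order thus stays open. Promoter shares of regions above input kept their direction with a window of 5 kb and at 0.01. For regions below input the direction turned at 0.01 for sox10 (35.5%, from 52.9%) and with 5 kb for tfap2B (67.7%, from 40.6%). The HH10 percentile of genes near tfap2B regions was 2.59 for regions overlapping the gene body or the 5 kb before it, and outside promoters it was 96.0 for sox10 and 95.3 for tfap2B. The planned gene lists by binding, HH10 gene list levels and motif content were not run, for lack of a gene name table and a genome. In the pull-downs 1 read was worth up to 2.34 scaled reads, and 0.734 to 2.43% of regions had the minimum of 1 read, against 4.80% and 5.97% in the inputs.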

Other observations

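The inputs were close to empty over many distal sites. Of the 13885 placed tested regions, 493 had at most 3 reads in both inputs, although the median placed region had 153 and 569 input reads. Of these 493, 3.25% were promoters, 54.0% were intergenic and 38.5% intronic, at a median of 24.4 kb from a TSS. Both pull-downs had reads there, with medians of 204 and 257 scaled reads for sox10 and 47.4 and 68.7 for tfap2B. They make up 24.99% of the placed regions above input for sox10 and 32.2% of those for tfap2B.

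Across placed regions the tfap2B libraries correlated with the inputs at Pearson's r of 0.21 to 0.55, and the sox10 libraries at -0.23 to -0.03. Across unplaced sequences tfap2B replicate 1 correlated with inputs 1 and 2 at 0.16 and 0.25, and tfap2B replicate 2 at 0.06 and 0.04. The sox10 libraries lay between -0.05 and 0.05 there, so the contrast was smaller. These correlations are across regions, which are not independent replicates. Across unplaced sequences the sox10 and tfap2B libraries correlated at 0.74 to 0.90, and across placed ones at 0.27 to 0.58.

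Of the placed regions below input, 10.8% for sox10 and 15.9% for tfap2B lay on chromosome Z, which holds 8.01% of the placed tested regions. On chromosome W, 17 of 141 genes had at least 10 counts at HH10, and on Z 594 of 1233. The 37 mitochondrial genes all had 0 counts, so a share of mitochondrial reads cannot be given for this library.

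The region at 51086640 of chromosome 1, upstream of ENSGALG00000012290, had 388 and 555 scaled reads in sox10, 72.5 and 81.2 in tfap2B and 1.39 and 4.72 in input (log2 difference between the factors 2.58, limma adjusted p = 0.0202 in the fit without inputs). Exonic regions of that gene reached 4911 and 21446 in sox10 and 6041 and 1025 in tfap2B at 51096274, where the factors did not pass the test. These regions were chosen after their values were seen. The 2 regions inside the gene both overlapped its exons. Reads from introduced construct DNA, left open for ENSGALG00000016680, were not tested for this gene.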
